A study of Mus musculus with 8 samples.

How the data were processed

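RNA was sequenced from 8 libraries of mouse bone marrow adipocytes in 3 groups: Control (n = 2), GC (n = 3; 1e-06 M dexamethasone for 24 hours) and GC+GW9662 (n = 3). The deposited table gives TPM per gene, reads over gene length scaled to the same total in each library. Per the labels the tools were fastp, HISAT2 2.1.0 and featureCounts; their order, the genome build and the annotation are not stated, and Smart-Seq2 libraries carry no strand. Titles and bracketed labels number the control libraries differently (Control2 is C3); replicates are named here by the title. Numbers shared between groups showed no pairing: deviations from the group means of GC and GC+GW9662 libraries with 1 number correlated at -0.10, -0.12 and 0.08. Pairs of these groups with unlike numbers gave -0.10 to 0.14. So few libraries cannot exclude shared cultures or batches.

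The table held 54232 rows for 54134 genes. Of 98 symbols on more than 1 row, 96 had the same values on each, and each gene was used once. Gene symbols turned into dates were restored by Ensembl ID in 27 cases. Starts and ends were those of GENCODE M21 in 97.6% of rows, which gave exon lengths. Of 26812 genes above 0, 99.6% were whole multiples of 1 step per library (tolerance 0.02) at the M21 length (11679 genes) or at a length solved from the values (15038). Of 500 scrambled profiles 0 were. These profiles came only from genes with several reads in every library, so they give no baseline for genes seen in few libraries. The smallest length that fitted was taken, so the depths are estimates that may be too low. This step placed the depth at 27604446 and 29049782 reads in Control, 22090248, 31030980 and 30412303 in GC and 19569574, 19649619 and 20759487 in GC+GW9662, in replicate order. Amplified reads without molecular identifiers are not independent molecules, so depth bounds counting error only. Libraries of a group differed beyond counting noise in every pair, so none was a copy of another.

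Genes with at least 1 TPM in at least 2 libraries (14985) were compared as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), with a mean per group over all 8 libraries, an empirical Bayes prior that followed mean expression, two-sided tests and Benjamini-Hochberg adjustment at 0.05 within each of 3 comparisons. Genes opposed by GW9662 passed in GC against Control and, the other way, in GC+GW9662 against GC. They were counted beside independent lists and 20 simulated data sets without change. Tables were prepared and plotted in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

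Lists of genes, written before the data were examined, were tested with limma camera against all other tested genes (preset correlation 0.01, at least 5 tested members, adjusted over the lists of a comparison). Beside it they were tested with an estimated correlation and with fry. Estimating the correlation also cuts the degrees of freedom of camera to those of the fit. For prostaglandin genes in GC against Control the estimate was 0.01, like the preset, yet camera adjusted p went from 0.042 to 0.23. A call lost this way therefore need not come from correlated members. They covered glucocorticoid-induced genes, PPARγ target genes of lipid handling, adipocyte identity, fatty acid and triglyceride synthesis, cholesterol synthesis, p53 targets, senescence and cell cycle inhibitors, senescence-associated secretory genes, proliferation, prostaglandins and oxylipins, inflammatory NF-kB targets, interferon-stimulated genes, ER stress and the integrated stress response, immediate early genes, antioxidant Nrf2 targets, osteoblasts, bone marrow stroma, extracellular matrix and myofibroblasts, macrophages, osteoclasts, neutrophils, lymphocytes, erythroid and endothelial cells, and mitochondrially encoded genes. Lists of heat shock, iron and heme, autophagy, glycolysis and proteasome genes were added after the data were seen.

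Genes were named by a rule fixed before the data were examined. It took 10 genes in every comparison (Nr3c1, Pparg, Fkbp5, Tsc22d3, Fabp4, Adipoq, Cdkn1a, Cdkn2a, Ptgs2 and Il6). It also took the 8 largest rises and 8 largest falls among passing genes with at least 5 TPM in a group, no overlap between the groups and no clone or predicted-gene name. From each passing, treatment or senescence list it took up to 4 passing members with the smallest adjusted p, of which some are left out here, and it took the leading opposed genes. Some genes that the rule takes are not reported here. Genes outside the rule (Fth1, Cd68, Eng and the other members of untested lists, and the added lists) were chosen after their values were seen.

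Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, median-ratio scaling, quantile normalization, rescaling without mitochondrial and the top 20 genes, a constant prior, robust empirical Bayes, library weights, fits of the compared groups alone, replicate blocks by title or bracket number, a minimum log2 change of 1, leaving out each library, and camera on ranks. Removal of a loess trend on exon length (span 0.3) and limma voom on recovered reads were chosen after seeing the data. Tested on simulated data, the fit recovered 37 of 100 genes changed by 1 on the log2 scale and 86 of 100 changed by 2 in GC against Control (8 false calls), 46 and 88 of 100 in GC+GW9662 against GC (13 false calls), and made 0 false calls without change. The simulated noise was independent between genes and held no length trend, so these false-call counts need not hold for the real libraries. A length trend put into a library fell from a correlation of -0.74 to -0.01 after removal.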

Results

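The series measured RNA in mouse bone marrow adipocytes, made by driving bone marrow stem cells through 14 days of adipogenic differentiation in culture. Differentiated cells were either left as controls, given 1e-06 M dexamethasone (DEX, a synthetic glucocorticoid) for 24 hours, or given the same DEX together with GW9662, an inhibitor of the adipocyte transcription factor PPARγ, at a dose not given in the sources used here. The 8 libraries fell into 3 groups, Control (n = 2), GC (n = 3) and GC+GW9662 (n = 3), made with the Smart-Seq2 protocol, which amplifies full-length cDNA. Values are TPM per gene. The steps between low TPM values gave an estimated depth of 19569574 to 31030980 reads per library. In all, 14985 genes reached 1 TPM in at least 2 libraries and were tested. Group values below are mean ± SD over the 2, 3 and 3 libraries, and changes are log2(TPM + 1) ± SE from limma with Benjamini-Hochberg adjusted p. That scale understates the change of low genes. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these samples.

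The 3 groups separated clearly. Libraries of a group correlated at 0.947 or more across genes, against 0.78 to 0.906 between groups, and the first principal component (52.7% of the variance) set the GC libraries apart from all others. Fth1, the ferritin heavy chain that stores iron, took 13.3% to 13.5% of all TPM in the GC libraries and 3.69% to 3.91% elsewhere; it was named after its values were seen. GC replicate 1 stood apart within its group: its exon-length profile differed from that of GC replicates 2 and 3, with a median difference of 0.20 in the shortest of 10 equal bins of genes and -0.81 in the longest.

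The receptor, the target of the inhibitor and the best-known glucocorticoid target genes were among 10 genes reported in every comparison. Nr3c1, the glucocorticoid receptor, stood at 34.1 ± 2.48 TPM in Control, 16.2 ± 8.85 in GC and 5.74 ± 0.215 in GC+GW9662. Pparg, the target of GW9662, stood at 7.57 ± 1.81, 2.94 ± 0.598 and 17.6 ± 0.871 TPM. Fkbp5 and Tsc22d3, classical glucocorticoid-induced genes, were highest in the libraries labelled Control: Fkbp5 measured 446 ± 24.1, 58.5 ± 24.2 and 95.4 ± 14.3 TPM, and Tsc22d3 557 ± 21, 59.6 ± 7.70 and 429 ± 27.2 TPM in the same order. In the libraries labelled GC, Fkbp5 fell by 3.0 (log2, SE 0.33, limma adjusted p = 1.4e-04) and Tsc22d3 fell by 3.21 (SE 0.13, adjusted p = 8.7e-07), the opposite of their known response to DEX. Group names are therefore used below only as the libraries are labelled, and every direction drawn from them rests on those labels. The Nr3c1 call (GC against Control, -1.19 ± 0.44, adjusted p = 0.047) was lost without either control library, GC replicate 3 or any GC+GW9662 library, with adjusted p up to 0.18 and log2 from -1.55 to -0.69 over single omissions. GC replicate 1 held 6.56 TPM against 24.0 and 18.0 in GC replicates 2 and 3. Median-ratio scaling (-0.79, adjusted p = 0.095), quantile normalization (-0.67, 0.091) and removal of the length trend (-0.42, 0.19) also ended it. So did a pseudocount of 0.1 (0.052), no filter (0.090), rescaling without mitochondrial and top 20 genes (0.083), a constant prior (0.052), the compared groups alone (0.13) and the title-number block (0.067) (range over all alternatives 9.2e-06 to 0.19).

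**Figure D1:**
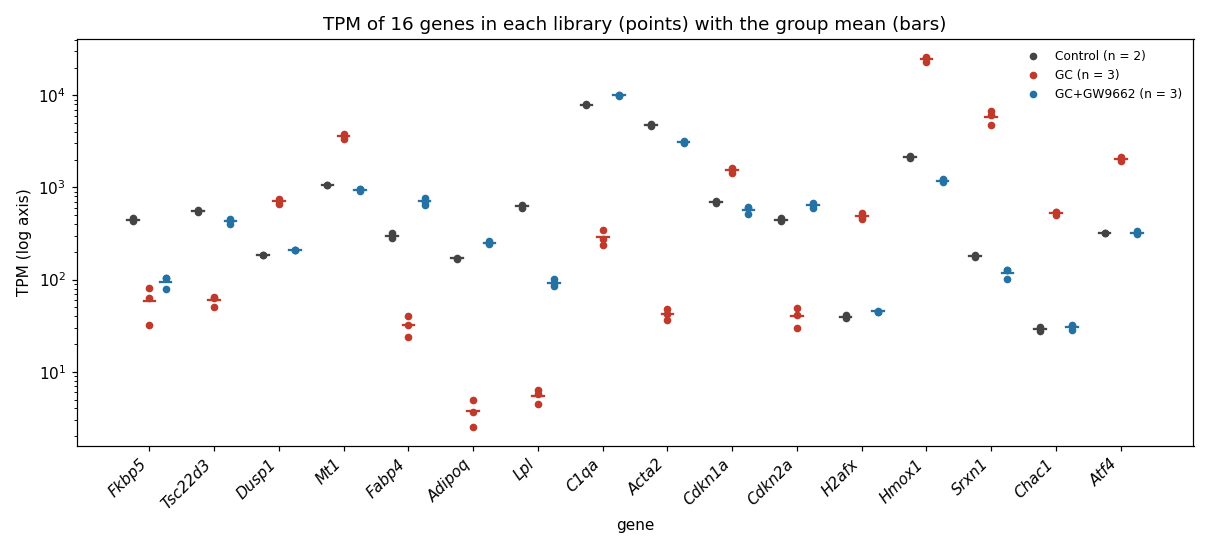
TPM of 16 genes on a log axis, 1 point per library, coloured by group as labelled, with a bar at each group mean (Control n = 2, GC n = 3, GC+GW9662 n = 3). Fkbp5 and Tsc22d3 were lower in the GC libraries than in Control, Hmox1, Srxn1, Chac1 and Atf4 were higher, and the GC+GW9662 mean lay nearer Control than GC for every gene shown except Fkbp5.

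The comparison of GC with Control asked how the differentiated cultures responded to the glucocorticoid, with cellular senescence as the study's theme. Macrophage genes such as Lyz2 (10681 TPM) and C1qa (7942 TPM) were abundant in Control. The changes below therefore cannot be assigned to adipocytes alone. In the libraries labelled GC, most genes of the fat-storage, connective tissue and macrophage lists were lower, and in the lists of oxidative and ER stress more genes rose than fell. None of these list calls held with an estimated correlation (lowest adjusted p = 0.22). That version of the test also has fewer degrees of freedom, so the losses need not come from correlated members. Of 14985 genes, 8291 passed the threshold, 2428 higher and 5863 lower, of which 1372 and 4263 differed at least 2-fold. The median of all genes was -0.38, and longer genes were lower: medians ran from 0.18 in the shortest of 10 bins by exon length to -1.09 in the longest. Scaling by the median ratio brought the median to -0.04 and the split to 3633 higher and 4415 lower, quantile normalization gave 4187 and 3915, and removing the length trend, an alternative chosen after seeing the data, gave 4262 and 4004.

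The largest falls were in Ms4a6c (907 to 5.77 TPM, -7.08 ± 0.17), F13a1, a transglutaminase subunit (291 to 1.34, -7.00 ± 0.27), Acta2, smooth muscle actin (4767 to 42.1, -6.80 ± 0.12), and Hpgd, which degrades prostaglandins (277 to 1.63, -6.79 ± 0.27). Next came the innate immune receptor gene Tlr8 (-6.76), the nucleotide receptor gene P2ry6 (-6.75) and the complement receptor gene C5ar1 (-6.68). Mrc1, the mannose receptor and a member of the macrophage list, followed (-6.66). The largest rises were in the small nuclear RNA genes Rnu11 (168 TPM in GC), Rnu5g (60.4) and Rnu1a1 (50.4), each listed at 0 in both control libraries. They were followed by Arc (6.51), the growth factor gene Hbegf (18.8 to 1149.9 TPM, 5.80 ± 0.28), Pou3f1 (5.65), the ubiquitin-like modifier gene Isg15 (5.49) and the matrix protease gene Mmp3 (17.8 to 778 TPM, 5.37 ± 0.13). The adjusted p of these 16 genes ranged up to 2.3e-04. Small nuclear RNAs have many near-identical copies, so their values are uncertain.

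Most tested genes of the fat-storage lists fell. Of 25 tested PPARγ target genes of lipid handling, 19 fell, 1 rose and 5 did not pass (camera adjusted p = 3.0e-04, and adjusted p = 0.22 with an estimated correlation). Lpl, which frees fatty acids from lipoproteins, stood at 621 ± 27.6 TPM in Control and 5.51 ± 0.969 in GC (-6.59 ± 0.15). Cidec and Plin1, lipid droplet coat genes, changed by -5.22 and -5.03, and Fabp4, a fatty acid carrier, went from 301 ± 28.8 to 32.1 ± 8.02 TPM (-3.21 ± 0.20, adjusted p = 7.2e-06). Of 18 adipocyte identity genes, 13 fell and 1 rose (camera adjusted p = 0.0039, 0.22 with an estimated correlation). Adipoq, the adipocyte hormone adiponectin, went from 170.3 ± 4.5 to 3.71 ± 1.23 TPM (-5.22 ± 0.20, adjusted p = 8.2e-07), Adig changed by -3.77 and Agpat2, an enzyme of triglyceride synthesis, by -2.69. Pparg itself fell by 1.12 (SE 0.21, adjusted p = 0.0026), a call that quantile normalization ended (-0.36, adjusted p = 0.13, range over the alternatives 5.3e-06 to 0.13). Fatty acid and triglyceride synthesis (10 of 15 fell and 1 rose, adjusted p = 0.023, 0.47 with an estimated correlation) was led by the desaturase genes Scd1 (-4.02) and Scd2 (-4.02). In cholesterol synthesis 19 of 21 genes fell and 1 rose (adjusted p = 1.5e-05, 0.22 with an estimated correlation), including Nsdhl (147 to 14.3 TPM) and Stard4 (34.2 to 1.98 TPM).

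Genes of other cell types moved with the GC label in the same libraries. Macrophage genes were abundant in Control and fell: of 23 tested, 21 fell and 1 rose (camera adjusted p = 2.5e-06, 0.22 with an estimated correlation). The complement genes C1qa (7942 ± 21.2 to 289 ± 55.3 TPM, -4.79 ± 0.15), C1qb (-4.05) and C1qc (-4.41) and the pore-forming gene Mpeg1 (-5.30) led the list. The member that rose was Cd68, a lysosomal protein gene, from 979 ± 32.1 to 2651 ± 403 TPM (1.43 ± 0.15, adjusted p = 1.2e-04), named after its values were seen. Extracellular matrix and myofibroblast genes fell in 28 of 30 cases with no rise (adjusted p = 3.1e-08, 0.30 with an estimated correlation), among them Acta2, Myl9 (-5.70) and Ctgf (-4.90). Bone marrow stromal genes (14 of 17 fell and none rose, adjusted p = 2.0e-04, 0.30 with an estimated correlation) included the chemokine gene Cxcl12 (166 to 13.7 TPM) and Pdgfrb (171 to 2.66). Osteoblast genes (13 of 14 fell and none rose, adjusted p = 1.6e-04, 0.23 with an estimated correlation) included the bone matrix gene Ibsp (-5.91) and the phosphatase gene Alpl (-4.49). Of 6 osteoclast genes 2 rose and 4 fell (adjusted p = 0.74). Of 5 neutrophil genes 1 rose and 2 fell (adjusted p = 0.76), and of 9 lymphocyte genes 1 rose and none fell (adjusted p = 0.052). The lymphocyte list passed as higher without Control replicate 2 (0.038), GC replicate 2 (0.039) or 3 (0.019), or GC+GW9662 replicate 2 (0.046) or 3 (0.048), and with either replicate block or ranks (range over the alternatives 0.019 to 0.45). Erythroid and endothelial lists had 1 and 4 tested members and were not tested as sets. Epor stood at 0.920, 0 and 0.913 TPM in Control, GC and GC+GW9662, and the stromal and endothelial gene Eng at 69.1, 8.62 and 17.3. The other 3 endothelial genes, Egfl7, Emcn and Flt1, stayed at or below 6.41 TPM in group means.

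The stress lists held more rises than falls. Among antioxidant Nrf2 target genes 12 of 21 rose and 6 fell (camera adjusted p = 0.0012, 0.23 with an estimated correlation). Hmox1, which breaks down heme, reached 24678 ± 1472 TPM against 2146 ± 50.5 in Control (3.52 ± 0.10, adjusted p = 2.5e-07), Srxn1 reached 5869 ± 974 against 180.4 ± 7.62 (5.00 ± 0.17), and the peroxide scavenger gene Prdx1 changed by 3.89, while Aldh3a1 fell by 3.08. Fth1 rose from 37274 to 134034 TPM (1.85 ± 0.11, adjusted p = 5.0e-06), a change that quantile normalization sets to 0. Fth1 and Prdx1 have processed pseudogenes that can share their reads. In the list of ER stress and the integrated stress response 11 of 24 rose and 6 fell (adjusted p = 7.6e-04, 0.22 with an estimated correlation): the transcription factor gene Atf4 went from 323 ± 1.31 to 2042 ± 82.6 TPM, its targets Chac1 and Trib3 changed by 4.13 and 2.97, and the ER chaperone gene Dnajb9 by 4.22. Immediate early genes, which answer stimuli within minutes, rose in 12 of 21 cases and fell in 6 (adjusted p = 0.0020, 0.41 with an estimated correlation), with Atf3 at 2.13, Fosb at 3.20 and Junb at 1.86. Interferon-stimulated genes went the other way, 16 of 23 lower and 3 higher (adjusted p = 0.023, 0.38 with an estimated correlation). Ifi27l2a fell from 145 to 13.4 TPM while Isg15 rose. Inflammatory NF-kB targets were mixed (8 rose and 11 fell of 26, adjusted p = 0.64). Mitochondrially encoded genes fell in 11 of 12 cases (adjusted p = 0.0020, 0.22 with an estimated correlation), mt-Nd1 from 10962 to 1088 TPM and mt-Cytb from 5420.4 to 1285.

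The list of senescence and cell cycle inhibitor genes did not pass in 1 direction. Of its 16 tested genes 7 rose and 5 fell (camera adjusted p = 0.19). It mixes inhibitor genes such as Cdkn1a with genes known to fall in senescence, such as Lmnb1. A test of 1 direction on this list therefore cannot decide whether senescence changed. Cdkn1a, which encodes p21, went from 697 ± 17.9 to 1538 ± 111 TPM (1.14 ± 0.11, adjusted p = 7.6e-05), and the histone gene H2afx rose (3.59 ± 0.11). Cdkn2a, which encodes p16 and ARF, fell from 445 ± 23.3 to 40.0 ± 9.71 TPM (-3.47 ± 0.19, adjusted p = 3.6e-06), and so did its neighbour Cdkn2b (-2.91 ± 0.12). Of 50 senescence-associated secretory genes 17 rose and 27 fell (adjusted p = 0.57): Mmp3 and Mmp10 (5.18) rose, Igfbp4 (-3.61) and Cxcl12 fell, and Il6 stood at 1.0 ± 0.335 and 1.07 ± 0.382 TPM (0.04 ± 0.26, adjusted p = 0.92). Of 22 p53 targets 5 rose and 6 fell (adjusted p = 0.57), with the stress gene Gadd45a at 4.80 and the death receptor gene Fas at -3.72. Proliferation genes fell in 22 of 35 cases and rose in 4 (adjusted p = 0.059); Ccnd1 fell by 3.98 and Pcna rose by 1.67. That list passed as lower without GC+GW9662 replicate 2 (0.0486) or 3 (0.0488), with the bracket-number block (0.040) and with ranks (0.035; range over the alternatives 2.6e-04 to 0.47). Prostaglandin and oxylipin genes fell in 19 of 30 cases and rose in 6 (adjusted p = 0.042, 0.23 with an estimated correlation), a call lost without GC replicate 2 (adjusted p = 0.089), with the bracket-number block (0.052) and with quantile normalization (adjusted p = 0.064, range over the alternatives 2.8e-06 to 0.23). Hpgd, Tbxas1 (-4.26) and Ptger2 (-2.82) fell, and Ptgs2, the inducible prostaglandin synthase, went from 6.08 ± 0.507 to 55.0 ± 28.4 TPM (2.83 ± 0.43, adjusted p = 8.2e-04).

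Glucocorticoid-induced genes went both ways: 5 of 25 rose, 15 fell and 5 did not pass (camera adjusted p = 0.48). Sult1a1 (-5.23) and Angptl4 (-4.58) fell with Fkbp5 and Tsc22d3, and Dusp1, a kinase phosphatase gene, rose from 186 ± 0.436 to 708 ± 45.6 TPM (1.92 ± 0.09). Angptl4 and Pdk4, which also fell, are on the list of PPARγ targets of lipid handling too, so their falls count in both lists. Adjusted over the list alone, the 23 lists gave the same counts, except 13 rising immediate early genes and 23 falling proliferation genes. Camera sets each list against all other genes, and the median of all genes was -0.38. Its direction was up for the p53, senescence, secretory and NF-kB lists although their medians were between -0.68 and -0.04. The secretory median (-0.68) lay below that of all genes, while the mean of that list was -0.30.

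**Figure D2:**
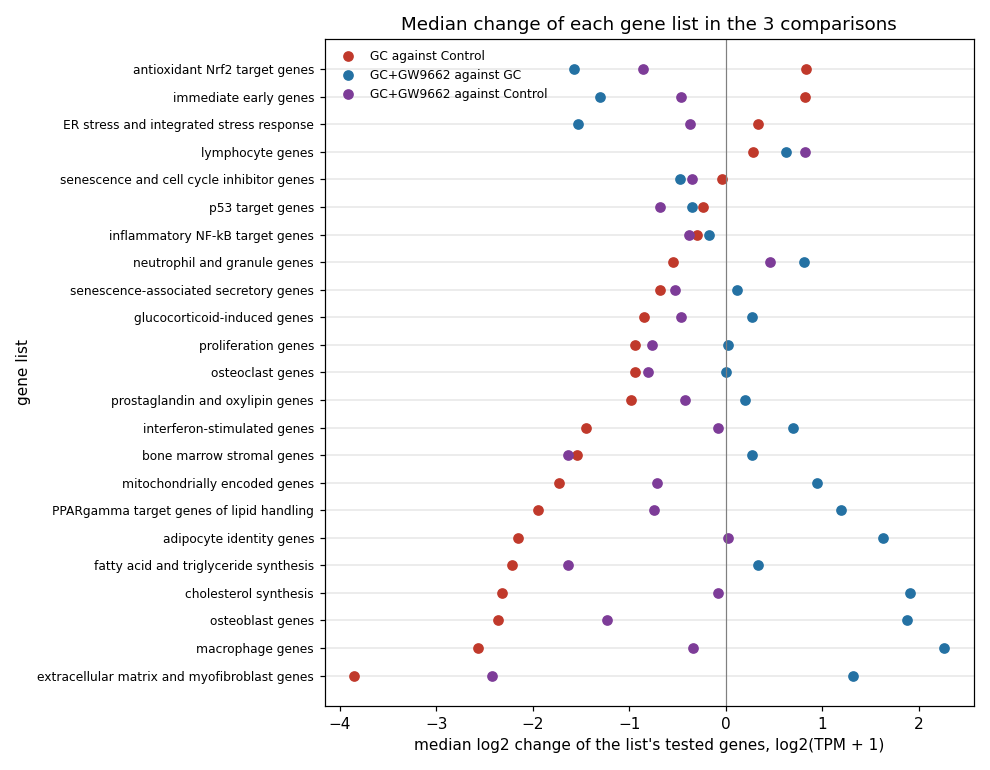
Median log2 change, on the log2(TPM + 1) scale, of the tested members of each of 23 gene lists, with 1 point per comparison and lists ordered by GC against Control. The extracellular matrix list had the lowest median in GC against Control (-3.85) and the Nrf2 list the highest (0.83). In GC+GW9662 against GC these medians were 1.32 and -1.57.

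The comparison of GC+GW9662 with GC asked what the PPARγ inhibitor changed in glucocorticoid-treated cells. Most gene groups that separated GC from Control differed in the opposite direction here. Of 25 PPARγ targets of lipid handling 15 were higher with the inhibitor and 3 lower. That is the reverse of what inhibition of PPARγ should do to its targets. This direction too rests on the labels, and an exchange of labels involving GC+GW9662 was not tested. With an estimated correlation no list passed (lowest adjusted p = 0.21). Of 14985 genes 9253 passed, 4236 higher and 5017 lower, with a median of -0.11 over all genes and medians from 0.40 in the shortest of 10 bins by exon length to -0.51 in the longest. On reads recovered from the TPM steps, limma voom, chosen after seeing the data, split 9223 calls into 5466 higher and 3757 lower. Median-ratio scaling gave 4907 higher and 4471 lower. Rescaling without mitochondrial and top 20 genes moved the split the other way, to 3801 higher and 5796 lower. Relative to GC, Pparg changed by 2.25 ± 0.19 (adjusted p = 3.4e-05). Nr3c1 was -1.18 ± 0.39 (adjusted p = 0.029), a call lost without GC replicate 2 or 3 or any GC+GW9662 library, with adjusted p up to 0.097 and log2 from -1.69 to -0.83, and also with no filter (0.061) and with voom (0.062).

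The largest rises were in Ccl9, a chemokine gene (7.08 to 852 TPM, 6.83 ± 0.29), Ms4a6c (6.76), Hpgd (6.37), P2ry6 (6.22), Acta2 (42.1 to 3127 TPM, 6.19 ± 0.11), C5ar1 (6.17), Ms4a6b (6.17) and Wisp2 (6.11). The largest falls were in Arc (-7.57), Hbegf (1149.9 to 9.04 TPM, -6.78 ± 0.25), Rnu11 (-6.48), Mmp3 (-6.38), Phlda1 (-6.15), Rnu5g, listed at 0 in the GC+GW9662 libraries, and the near-identical heat shock genes Hspa1a (-5.72) and Hspa1b (-5.70), whose reads cannot be told apart with certainty. Adjusted p was up to 4.3e-05 over the 16.

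Of 25 PPARγ targets of lipid handling 15 rose and 3 fell (camera adjusted p = 1.7e-04, 0.21 with an estimated correlation). Fabp4 reached 706 ± 66.1 TPM (4.44 ± 0.18, adjusted p = 8.2e-07), Lpl 92.8 ± 8.15 (3.86 ± 0.14), and Cidec and Plin1 differed by 4.93 and 4.36. Adipocyte identity genes rose in 12 of 18 cases and fell in 4 (adjusted p = 0.0012, 0.21 with an estimated correlation), with Adipoq at 251 ± 8.02 TPM (5.78 ± 0.18, adjusted p = 3.6e-07), Adig at 5.38 and the adipokine gene Cfd at 3.84. Cholesterol synthesis genes rose in 18 of 21 cases and fell in 2 (adjusted p = 4.2e-07, 0.21 with an estimated correlation), Nsdhl and Mvd by 3.17 and 2.88. Fatty acid and triglyceride synthesis was split, 6 higher and 4 lower of 15 (adjusted p = 0.22).

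Macrophage genes were higher in 19 of 23 cases and lower in 1 (adjusted p = 4.2e-07, 0.21 with an estimated correlation), with C1qa at 9986 ± 220.4 TPM (5.12 ± 0.13), C1qb at 3.90 and the Fc receptor gene Fcgr3 at 2.88. Cd68 differed by -2.15. Matrix genes rose in 18 of 30 and fell in 2 (adjusted p = 3.6e-05, 0.49 with an estimated correlation), Myl9 by 4.65 and Ctgf by 3.17. Osteoblast genes rose in 11 of 14 with none lower (adjusted p = 3.1e-04, 0.26 with an estimated correlation), Ibsp by 3.33. Interferon-stimulated genes rose in 14 of 23 and fell in 3 (adjusted p = 0.0023, 0.26 with an estimated correlation), Ifi27l2a at 4.61 and Isg15 at -4.66. Mitochondrially encoded genes rose in 7 of 12 and fell in 2 (adjusted p = 0.017, 0.26 with an estimated correlation), mt-Nd1 by 2.86. This call was lost with quantile normalization (adjusted p = 0.077) and with the length trend removed (adjusted p = 0.15, range over the alternatives 4.7e-05 to 0.26). Stromal genes gave 7 rises and 3 falls of 17 (adjusted p = 0.11), osteoclast genes 2 and 2 of 6 (adjusted p = 0.85), neutrophil genes 3 and 1 of 5 (adjusted p = 0.27), and lymphocyte genes 5 and 1 of 9 (adjusted p = 0.16). The lymphocyte list passed without GC replicate 1 (0.048) and the stromal list with the length trend removed (0.020), with ranges over the alternatives of 0.040 to 0.62 and 0.0016 to 0.70.

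In 3 stress lists more genes fell than rose with the inhibitor. Nrf2 targets fell in 14 of 21 cases and rose in 6 (adjusted p = 0.0064, 0.31 with an estimated correlation), Hmox1 to 1184 ± 45.1 TPM (-4.38 ± 0.09), Srxn1 by -5.61 and the cystine transporter gene Slc7a11 by -4.37. The ER stress and integrated stress list fell in 18 of 24 cases and rose in 5 (adjusted p = 7.3e-04, 0.21 with an estimated correlation), with Atf4, Chac1 and Dnajb9 at -2.66, -4.05 and -4.12. Immediate early genes fell in 13 of 21 and rose in 2 (adjusted p = 0.0062, 0.52 with an estimated correlation), Fosl1 by -4.05 and Atf3 by -2.41. NF-kB targets were again mixed (9 rose and 7 fell of 26, adjusted p = 0.91).

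Of the senescence and cell cycle inhibitor genes 4 rose and 8 fell of 16 (adjusted p = 0.39). Cdkn1a was lower at 573 ± 51.9 TPM (-1.42 ± 0.10, adjusted p = 1.3e-05), as were H2afx (-3.40) and the deacetylase gene Sirt1 (-4.36), and Cdkn2a was higher at 644 ± 41.0 TPM (4.0 ± 0.17, adjusted p = 1.0e-06), as was Cdkn2b (2.86). Secretory genes split into 18 higher and 17 lower of 50 (adjusted p = 0.97), with Mmp10 listed at 0 in the GC+GW9662 libraries, Cxcl12 at 3.07, Igfbp4 at 3.25 and Il6 at 1.08 ± 0.451 TPM (0.00 ± 0.23, adjusted p = 0.99). The p53 targets gave 7 rises and 11 falls of 22 (adjusted p = 0.63), Gadd45a at -4.93 and Fas at 3.05, and proliferation genes 12 and 8 of 35 (adjusted p = 0.38), Ccnd1 at 2.54 and Pcna at -1.18. Prostaglandin and oxylipin genes gave 13 rises and 8 falls of 30 (adjusted p = 0.066), with Alox5ap at 1245 TPM, Tbxas1 at 3.79 and Ptgs2 at 1.46 ± 0.211 TPM (-4.35 ± 0.39, adjusted p = 4.5e-05). This list passed without GC replicate 1 (adjusted p = 0.044) and with quantile normalization (0.046; range over the alternatives 7.8e-06 to 0.26). Glucocorticoid-induced genes gave 12 rises and 9 falls of 25 (adjusted p = 0.40): Tsc22d3 (2.83 ± 0.12) and Sult1a1 (4.76) were higher, the metallothionein genes Mt1 (-1.92) and Mt2 (-1.97) were lower. Fkbp5 missed the threshold (0.78 ± 0.30, adjusted p = 0.0501). It passed without GC replicate 1 (0.41, adjusted p = 0.038) or 2 (1.05, adjusted p = 0.013) and under 6 planned or added alternatives, among them median-ratio scaling (0.0045; range over the alternatives 4.7e-05 to 0.13). Adjusted over the list alone, counts were the same, except 13 rises and 10 falls of glucocorticoid-induced genes and 8 rises of mitochondrial genes. The secretory list had a median of 0.11 and a test direction of down, and the NF-kB list -0.18 and up.

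Genes that passed in both comparisons mostly went opposite ways. There were 4916 opposed genes, of which 1960 were higher in GC and lower with GW9662, and 2956 were lower in GC and higher with GW9662. The split between these directions depended on the scaling: 2419 and 2690 with the median ratio, 2825 and 2426 with quantile normalization, 2464 and 2531 after rescaling, and 3039 and 2947 with the length trend removed. Voom on recovered reads moved it the other way, to 1770 and 3430. Lists of the main sizes drawn independently would share 813 and 1657. Only 25 genes were higher in both comparisons, where independent lists would share 686, and 313 were lower in both, against 1963. Of the genes higher in GC, 80.7% were lower with GW9662, and of those lower in GC, 50.4% were higher, on TPM as deposited. The opposed genes with the largest changes were Arc, Hbegf, Mmp3, Pou3f1, Rnu11 and Rnu5g in the first direction and Acta2, C5ar1, Hpgd, Ms4a4a, Ms4a6c and P2ry6 in the second. Here too the changes cannot be assigned to adipocytes alone. Of 23 macrophage genes 21 fell and 1 rose in GC against Control, and 19 rose and 1 fell in GC+GW9662 against GC. Ms4a4a stood at 3237 ± 101, 41.9 ± 13.8 and 2688 ± 380.2 TPM in Control, GC and GC+GW9662. Fold changes of the 2 comparisons correlated at -0.66 across genes, which are not independent replicates, with a covariance of -1.134. Because both use the GC libraries, unchanged simulated groups gave -0.44 and -0.037, with 0 opposed calls over 20 simulations. Without change almost no gene passes, so that 0 gives no baseline for the opposed count. A change confined to the shared GC libraries would also give opposed calls. Neither the simulations nor the independent lists take it into account. Opposite signs were no more common than in the simulations, at 64.3% of genes against 64.8%.

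The comparison of GC+GW9662 with Control showed what still differed when both compounds were given. Most matrix and stromal genes were lower than in Control, calls that were lost with an estimated correlation (adjusted p = 0.89 for each). Adipocyte identity genes went both ways (5 higher and 6 lower of 18). Of 14985 genes 9398 passed, 2114 higher and 7284 lower, and 2570 of the opposed genes were not among them. Without Control replicate 1, 5902 genes passed, 916 higher and 4986 lower, and without Control replicate 2, 6895 passed, 1292 higher and 5603 lower. The split followed exon length closely, from a median of 0.59 in the shortest bin to -1.68 in the longest, where 18 genes rose and 1361 fell. Median-ratio scaling moved the median of all genes from -0.49 to 0.00 and gave 4270 higher and 4939 lower, and quantile normalization gave 4216 and 4443. With the length trend removed 6960 genes passed, 3550 higher and 3410 lower, and 419 of them had passed in the opposite direction. Limma voom on recovered reads gave 3553 and 5524.

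**Figure D3:**
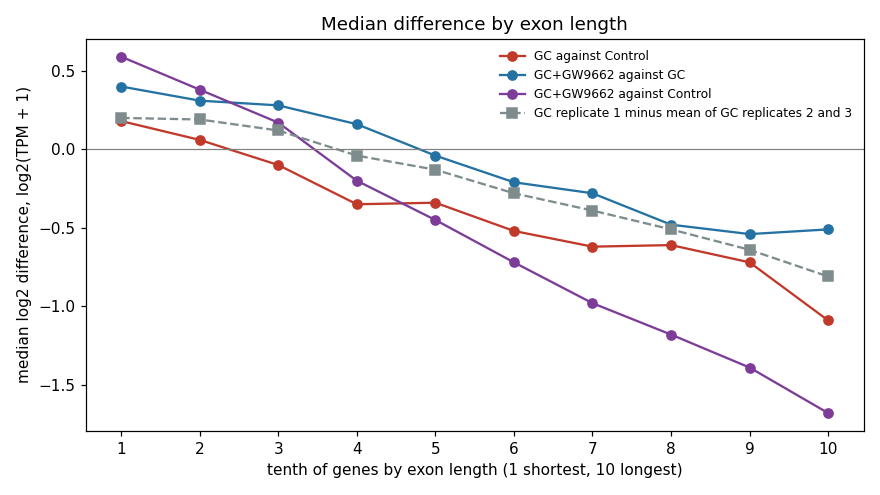
Median log2 difference, on the log2(TPM + 1) scale, of genes in each of 10 bins of exon length, with a line for each comparison and a dashed line for GC replicate 1 minus the mean of GC replicates 2 and 3. In GC+GW9662 against Control the median ran from 0.59 in the shortest bin to -1.68 in the longest, and within the GC group from 0.20 to -0.81.

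Among the largest falls were Postn, a matrix protein gene (293 to 22.6 TPM, -3.64 ± 0.72), Colec12 (-3.59), Dennd4c (-3.50), the copper transporter gene Atp7a (-3.45), Pik3c2a (-3.44), the ubiquitin ligase gene Nedd4 (-3.44) and the mitochondrial tRNA gene mt-Tl1 (-3.44 ± 1.18). The largest rises were in the T cell receptor segments Trbj1-4 (7.20 TPM in GC+GW9662) and Trbj1-6 (7.68 TPM), both listed at 0 in Control, then Rps27rt (2.37), Snord42b (2.06 ± 0.69), Mir23a (2.05), the calcium-binding neutrophil gene S100a8 (22.8 to 77.3 TPM, 1.73 ± 0.29), the ribosomal gene Rps14 (2052 to 6438 TPM, 1.67 ± 0.30) and Scarna2 (1.61). Ribosomal genes share reads with their pseudogenes, and most of the risers are very short. Adjusted p was up to 0.033 over the genes named here. The mt-Tl1 call was lost without either control library or GC+GW9662 replicate 1 or 3 (adjusted p up to 0.17, log2 from -4.38 to -2.85 over single omissions), the Snord42b call without Control replicate 2 or any GC+GW9662 library (up to 0.24, log2 from 1.11 to 3.01), and the Trbj1-6 call without Control replicate 1 (0.051, log2 from 2.47 to 3.54). Under 5 other alternatives mt-Tl1 did not pass (range 7.9e-04 to 0.17), and under 3 Snord42b did not (range 0.0083 to 0.24).

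Matrix and myofibroblast genes were lower in 28 of 30 cases and higher in 1 (camera adjusted p = 1.5e-04, 0.89 with an estimated correlation), Col3a1 from 219 ± 7.55 to 27.0 ± 1.72 TPM (-2.98 ± 0.19) and Ctgf by -1.73. Stromal genes were lower in 16 of 17 and higher in 1 (adjusted p = 0.0067, 0.89 with an estimated correlation), the stromal transcription factor gene Ebf1 by -2.67 and Pdgfrb by -2.42. Lymphocyte genes rose in 6 of 9 with none lower (adjusted p = 3.8e-04, 0.89 with an estimated correlation), at low levels: Cd2, a T cell adhesion gene, went from 1.85 ± 0.411 to 5.83 ± 1.20 TPM. No other list written before the data were examined passed. PPARγ targets of lipid handling gave 3 rises and 15 falls of 25 (adjusted p = 0.44): the fatty acid transporter gene Cd36 (-1.22) and Lpl (-2.73 ± 0.15) were lower, and Fabp4 was higher (1.23 ± 0.20, adjusted p = 0.0024), as was Pparg (1.13 ± 0.21, adjusted p = 0.0033). Adipocyte identity genes gave 5 rises and 6 falls of 18 (adjusted p = 0.41), macrophage genes 3 and 12 of 23 (adjusted p = 0.68), cholesterol synthesis 7 and 9 of 21 (adjusted p = 0.41) and fatty acid synthesis 2 and 12 of 15 (adjusted p = 0.37). With the length trend removed the macrophage list passed as lower (adjusted p = 0.033), as it did with quantile normalization (0.027), cholesterol synthesis as higher (0.0082) and the mitochondrial list as lower (0.0034), with ranges over the alternatives of 0.0011 to 0.92, 0.0082 to 0.89 and 7.7e-04 to 0.89. Rises and falls were 1 and 14 of 24 for ER stress (adjusted p = 0.68), 2 and 14 of 21 for Nrf2 targets (adjusted p = 0.41), 1 and 12 of 21 for immediate early genes (adjusted p = 0.45), 3 and 9 of 23 for interferon-stimulated genes (adjusted p = 0.48) and 5 and 12 of 26 for NF-kB targets (adjusted p = 0.45). They were 2 and 9 of 14 for osteoblast genes (adjusted p = 0.41), 0 and 4 of 6 for osteoclast genes (adjusted p = 0.41), 1 and 2 of 5 for neutrophil genes (adjusted p = 0.45) and 2 and 8 of 12 for mitochondrial genes (adjusted p = 0.45).

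Among glucocorticoid-induced genes 2 rose and 15 fell of 25 (adjusted p = 0.43), and after median-ratio scaling 8 were higher and 8 lower. The values included Klf9 at -3.02 ± 0.36, Zbtb16 at -1.83, Pdk4 at -1.68, Glul at -0.71 and Fkbp5 at -2.22 ± 0.33 (adjusted p = 0.0020). With the length trend removed these were -2.12, -0.84, -1.15, -0.24 and -0.75. Tsc22d3 was -0.38 ± 0.13 (adjusted p = 0.033). Its sign turned with median-ratio scaling (0.28, adjusted p = 0.0503), with the length trend removed (0.40, adjusted p = 0.0097) and with voom (0.10, adjusted p = 0.39, range over the alternatives 6.5e-04 to 0.39). Glul lost its call with median-ratio scaling (-0.06, adjusted p = 0.66, range 3.0e-06 to 0.66). Nr3c1 was lower (-2.38 ± 0.44, adjusted p = 0.0032). Senescence and cell cycle inhibitor genes gave 2 rises and 6 falls of 16 (adjusted p = 0.85): the lysosomal galactosidase gene Glb1 was lower (-1.40), Cdkn2d higher (1.01), Cdkn2a at 0.53 ± 0.19 (adjusted p = 0.039) and Cdkn1a at -0.29 ± 0.11 (adjusted p = 0.054), the last turning to 0.37 with median-ratio scaling (adjusted p = 0.033), 0.26 without the length trend (adjusted p = 0.044) and 0.19 with voom (adjusted p = 0.12, range 0.0041 to 0.23). Cdkn1a passed as lower without GC replicate 1 (adjusted p = 0.025) or 2 (0.046), with library weights (0.0041), quantile normalization (0.012), the filter of 5 TPM (0.0493) and the compared groups alone (0.043). The calls of Tsc22d3, Adipoq (0.56 ± 0.20, adjusted p = 0.042) and Cdkn2a were each lost without either control library, GC replicate 3 or any GC+GW9662 library (adjusted p up to 0.17, 0.16 and 0.17). All 3 also missed the threshold with no filter, a constant prior and the title-number block, and Adipoq and Cdkn2a with quantile normalization (0.12 and 0.32) and without the length trend (0.14 and 0.23). Tsc22d3 also missed it with the bracket-number block (0.079) and rescaling (0.061), and Adipoq with a pseudocount of 0.1 (0.079). Secretory genes gave 7 rises and 27 falls of 50 (adjusted p = 0.85), with Hgf at -2.24, Mmp3 at -1.0, which quantile normalization brought to -0.04 (adjusted p = 0.81, range 2.1e-06 to 0.81), and Il6 at 0.04 ± 0.26 (adjusted p = 0.90). The p53 targets gave 3 and 13 of 22 (adjusted p = 0.73), Plk2 lower (-2.15) and Ei24 higher (1.11), and proliferation genes 2 and 22 of 35 (adjusted p = 0.42), with Ccnd1 at -1.44 and Rrm2 at -0.88, the latter not passing after median-ratio scaling (-0.23, adjusted p = 0.15, range 1.9e-06 to 0.15). Prostaglandin and oxylipin genes gave 3 and 13 of 30 (adjusted p = 0.85), with Pla2g4a at -1.78 and Ptgs1 at -1.29. Ptgs2 (-1.53 ± 0.43, adjusted p = 0.015) lost its call without Control replicate 1 or 2 (adjusted p = 0.065 and 0.079), and with a pseudocount of 5, quantile normalization, the length trend removed or voom (range 1.3e-05 to 0.11). Adjusted over the list alone, counts were the same, except 16 falls of PPARγ targets, 8 rises in cholesterol synthesis, 14 falls of p53 targets and 10 falls of osteoblast genes. Median and test direction differed in sign for the cholesterol, senescence, NF-kB and interferon lists, and the adipocyte identity list had a median of 0.02, a mean of -0.22 and a test direction of up.

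Key genes lie at these positions in the deposited table: Fkbp5 (ENSMUSG00000024222) on chromosome 17 from 28399095 to 28517524, and Tsc22d3 (ENSMUSG00000031431) on chromosome X from 140539528 to 140600659. Nr3c1 (ENSMUSG00000024431) lies on chromosome 18 from 39410545 to 39491301, and Pparg (ENSMUSG00000000440) on chromosome 6 from 115360951 to 115490399. Cdkn1a (ENSMUSG00000023067) spans 29090979 to 29100722 on chromosome 17 and Cdkn2a (ENSMUSG00000044303) 89274471 to 89294653 on chromosome 4. Adipoq (ENSMUSG00000022878) spans 23146536 to 23158028 on chromosome 16 and Hmox1 (ENSMUSG00000005413) 75093621 to 75100589 on chromosome 8. The values count reads over exons of the whole gene, so transcripts of Cdkn2a, or of any other gene, are not told apart. The build is not given in the sources used here, but 97.6% of rows have the start and end of the GENCODE M21 annotation of GRCm38.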

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

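Removal of the length trend and limma voom on recovered reads were chosen after seeing the data. All other alternatives were planned; count tests were not run because the table holds TPM. Of 73 counts of passing genes or lists under alternatives other than leaving out a library, 67 stayed within 1.5 times the main count. A similar count does not mean the same genes. With the length trend removed, 4828 of the 9398 main calls of GC+GW9662 against Control passed in the same direction. For GC against Control 6272 of 8291 did, and for GC+GW9662 against GC 8226 of 9253. With quantile normalization these shared calls were 6460, 6341 and 8805 in the same order. Genes opposed by GW9662 rose to 7679 with library weights. With a minimum log2 change of 1, GC+GW9662 against GC gave 5786 genes, GC+GW9662 against Control 5854 and opposed genes 2689, fewer by construction. Gene lists passing in all comparisons went from 28 to 0 with an estimated correlation, which also lowers the degrees of freedom. They went to 60 with fry, which does not compare a list with other genes.

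Leaving out each library in turn gave 5901 to 9259 genes in GC against Control, 7337 to 10801 in GC+GW9662 against GC, 5902 to 10317 in GC+GW9662 against Control, 3810 to 5747 opposed genes and 28 to 30 gene lists. The lowest count of GC+GW9662 against Control came without Control replicate 1, where the remaining control library was assumed to vary like the other groups.

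Directions reversed in these cases, and the cause was not tested. In GC against Control, fry turned the p53 (adjusted p = 0.38), secretory (0.15) and NF-kB (0.012) lists down. The secretory list also turned with the length trend removed (0.58), quantile normalization (0.66) and ranks (0.95), and Il6 turned with library weights (-0.24). In GC+GW9662 against GC, the secretory list turned with median-ratio scaling (0.95) and the bracket-number block (0.998), and Il6 with the length trend removed (-0.14), a pseudocount of 0.1 (-0.01), quantile normalization (-0.04) and rescaling (-0.08).

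In GC+GW9662 against Control, fry turned the adipocyte identity (0.11), cholesterol (0.25), senescence (0.022), NF-kB (0.093), interferon (0.016) and neutrophil (0.37) lists. Median-ratio scaling turned the glucocorticoid, immediate early and macrophage lists (each 0.88), the p53 list (0.74), and the prostaglandin and ER stress lists (each 0.63), with Tsc22d3 at 0.28 and Cdkn1a at 0.37. Length-trend removal turned the p53 (0.84) and prostaglandin (0.60) lists, Tsc22d3 (0.40) and Cdkn1a (0.26). Voom turned Tsc22d3 (0.10) and Cdkn1a (0.19), quantile normalization the proliferation (0.94) and prostaglandin (0.42) lists, and ranks the prostaglandin list (0.93).

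Some fits that left out a library also reversed a direction. Over all such fits the adjusted p was 0.86 to 0.97 for the secretory list and 0.78 to 0.99 for the NF-kB list in GC+GW9662 against GC, and 0.78 to 0.98 for the prostaglandin list in GC+GW9662 against Control. Il6 ranged from -0.13 to 0.21 in GC against Control, from -0.13 to 0.19 in GC+GW9662 against GC and from -0.13 to 0.23 in GC+GW9662 against Control. Of 2921 other values of named genes, 2847 kept direction and side of the threshold, as did 524 of 621 for lists; without a library, 1513 of 1568 and 536 of 552 did.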

Other observations

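The tests of exchanged labels, loss of long transcripts and the macrophage share, and the lists added here, were chosen after the result was seen. The added lists were not tested under other scalings, with the length trend removed or without single libraries. Of 31 proteasome subunit genes 27 rose and none fell in GC against Control (camera adjusted p = 5.2e-13, 0.064 with an estimated correlation), Psmd4 from 169 to 788 TPM. In GC+GW9662 against GC 1 rose and 22 fell (camera adjusted p = 6.9e-05, 0.32 with an estimated correlation). In GC+GW9662 against Control 16 rose and 8 fell, and the list passed as higher (camera adjusted p = 0.0041, 0.75 with an estimated correlation). Heat shock and chaperone genes rose in 4 and fell in 2 of 18 cases in GC against Control (adjusted p = 0.026, 0.51 with an estimated correlation), with Dnajb1 from 54.0 to 435 TPM. In GC+GW9662 against GC 3 rose and 14 fell (camera adjusted p = 0.0073, 0.32 with an estimated correlation). In GC+GW9662 against Control 2 rose and 13 fell (camera adjusted p = 0.36).

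Iron and heme handling genes rose in 6 and fell in 4 of 14 cases in GC against Control (adjusted p = 0.026, 0.44 with an estimated correlation), with the ferritin light chain gene Ftl1 from 4684 to 16269 TPM, and 2 rose and 9 fell with GW9662. Of 21 autophagy and lysosome genes 7 rose and 3 fell (adjusted p = 0.053), with Sqstm1 from 836 to 4966 TPM and Gabarapl1 from 302 to 1312, and 3 rose and 14 fell with GW9662. Of 16 glycolysis genes 4 rose and 9 fell (adjusted p = 0.85), and 2 rose and 8 fell with GW9662. Camera adjusted p in GC+GW9662 against GC was 0.011 for iron and heme, 0.017 for autophagy and lysosome and 0.10 for glycolysis genes. With an estimated correlation it was 0.32 for each. In GC+GW9662 against Control, rises and falls were 2 and 7 for iron and heme genes (camera adjusted p = 0.57). They were 4 and 14 for autophagy and lysosome genes (0.57) and 0 and 10 for glycolysis genes (0.36).

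Of the 15 glucocorticoid-induced genes that fell in the libraries labelled GC, 12 stayed lower with the length trend removed and 12 stayed lower after median-ratio scaling. These values argue against a length trend, or dilution by a few very abundant transcripts, as the whole cause. An exchange of the Control and GC labels would leave the GC+GW9662 libraries, labelled as given the same DEX, near the libraries labelled Control. In size, 10 of the 15 lay nearer Control than GC there, such as Tsc22d3 at -0.38 relative to Control, against -3.21 in GC. Yet 10 of the 15 were called lower in GC+GW9662 against Control. After median-ratio scaling 9 lay nearer Control, 6 were called lower and 3 higher, and with the length trend removed 10 lay nearer Control, 9 were called lower and 2 higher. Another 5 rose in GC against Control as labelled (Cdkn1c, Dusp1, Mt1, Mt2 and Nfkbia, by 0.82 to 2.77), which an exchange would turn into falls under DEX. The exchange cannot be told apart from the labels as given, because GW9662 differs between these groups too and the members went both ways. Angptl4 and Pdk4, both among the 15, are also on the PPARγ target list. Glucocorticoid in the culture medium, a fading response by 24 hours and other biological differences were not tested and stay open.

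Far more genes were lower than higher in GC+GW9662 against Control. The longest and shortest of 10 bins of genes by exon length differed by -2.27 there, but by at most 0.18 between libraries of the Control or GC+GW9662 group. This argues against a loss of long transcripts that varies from library to library among those compared. Outside this comparison, GC replicate 1 did differ in this way from GC replicates 2 and 3 (-1.13 and -0.82). A loss shared by all libraries of a group is confounded with the treatments and stays open, as does an effect of the treatments on long transcripts. The scaling of the libraries stays open too, since median-ratio scaling, which centres the changes by construction, gave 4270 higher and 4939 lower genes.

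Macrophage genes were lower in the libraries labelled GC. If only macrophages expressed them, a lower share of macrophages would lower them alike. The log2 changes of 18 abundant members, each at least 100 TPM in Control, had an SD of 2.04, from -6.66 to 1.43. Their median SE was 0.18, and Cd68 rose. Under that assumption these values argue against share as the only cause. Whether other cells in the cultures also expressed these genes was not tested, and with such a source the spread cannot decide. All 21 members that fell stayed lower with the length trend removed, against a length trend. A change in the macrophages themselves, with or without a change of share, was not tested. For GC+GW9662 against GC, the 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 8442 genes on these libraries alone and the highest other split 0. Every other split mixes libraries of both groups, which puts the group difference into the spread. That 0 therefore gives no baseline for the real split.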
